A study of Saccharomyces cerevisiae with 17 samples.

How the data were processed

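Total RNA of the strains BM45 and VIN13, sampled at days 2, 5 and 14 in Colombar must, was labelled with biotin and hybridised to Affymetrix yeast arrays, which carry probe sets for Saccharomyces cerevisiae and Schizosaccharomyces pombe. Per the labels, the authors summarised the scans with Affymetrix Expression Console, and the values used here are the deposited intensities, 1 per probe set and array, linear and without missing values. The version, the algorithm of summarisation and normalization and any background correction are not given in the sources used here. The 17 columns already lay at like levels, and they held 10928 probe sets with values from 0.000233 to 30409. Groups were strain and day as labelled, with 2 arrays of BM45 at day 2 and 3 of every other group.

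The array annotation listed 7245 of the 10928 probe sets, and 3683 were not listed. A single gene was given for 7244, of which 5498 were of S. cerevisiae, for 5449 genes, and 1746 of S. pombe, and 1 probe set with several genes was left out. For the 47 genes with more than 1 probe set the one with the highest mean over the 17 arrays was used, and 12 symbols were updated to current names. Intensities were taken as log2(value + 16), with no further normalization and no filter on dim genes. A background bound was set at the 95th percentile of the S. pombe probe sets, averaged over arrays, which was 6.8667 on that scale or an intensity of 100.7. Of the tested genes 5116 had a mean above it and 333 below. Control probe sets were used only for ratios of 3' to 5' signal and for the 25S ribosomal RNA, and the other S. pombe probe sets and those not listed were left out of the tests.

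One linear model with a mean per group was fitted to the 17 arrays with lmFit and eBayes of limma 3.58.1 under R 4.3.3, giving 11 residual and 3.806 prior degrees of freedom and a prior SD of 0.158. The 10 contrasts were day 5 against day 2 and day 14 against day 5 in each strain, VIN13 against BM45 at each day and averaged over the days, and the difference of each time change between the strains. P-values were two-sided and adjusted by Benjamini and Hochberg over the 5449 genes of a contrast, and a gene was called at an adjusted p under 0.05, with calls of at least 2-fold counted beside. Where a group lay below the background bound a lower bound of the fold was computed with each of its arrays set to the higher of its value and the bound. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

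Before the data were examined, 28 gene lists were fixed from textbook knowledge: glycolysis and ethanol formation, hexose transporters and sensors, cytosolic ribosomal proteins, ribosome biogenesis, heat shock proteins and chaperones, general stress response, trehalose and glycogen metabolism, tricarboxylic acid cycle, respiratory chain and ATP synthase, gluconeogenesis with glyoxylate and C2 metabolism, peroxisomal beta-oxidation, nitrogen catabolite repression, amino acid biosynthesis, sulfate assimilation and methionine, higher alcohol and ester formation, ergosterol biosynthesis, hypoxic and anaerobic genes, seripauperins, flocculation and adhesion, thiamine and vitamin B6 synthesis, iron uptake, zinc response, phosphate response, glycerol and osmotic response, vacuolar proteolysis and autophagy, cell cycle with DNA replication and histones, mating with haploid cell markers, and meiosis and sporulation with spore markers. The ribosomal protein list was set by a pattern of names that also took RPP1, a subunit of ribonuclease P.

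Each list was tested with camera of limma at its preset correlation of 0.01, adjusted over the 28 lists of a contrast, and again with a correlation estimated per list. With the preset, 87 of 280 tests were called and 109 had an unadjusted p under 0.05. With the estimated correlation camera called 0 of the 280, 12 had an unadjusted p under 0.05, and the lowest adjusted p was 0.161. Members called are counted over all genes tested and adjusted over the list alone.

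Genes named in the text were chosen by a rule set before the data were examined. It took, in each contrast, the 5 largest increases and the 5 largest decreases among called genes whose brighter group lay above the background bound and whose arrays did not overlap between a pair of groups. To these it added up to 3 called members with the largest change of each list, or up to 2 members by smallest p of a list without calls, and the text names fewer than the rule allows. Near-identical families were named as open to cross-hybridisation.

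Alternatives set in advance changed one choice at a time: pseudocounts of 1 and 64, quantile normalization, centring on the median gene, the mean over probe sets, all probe sets in the fit, dim genes left out, eBayes with trend and robust settings, arrayWeights, only the arrays compared, replicate number as a block, an adjusted p under 0.01, a change of at least 2-fold, and each array left out in turn. After the data were seen, a fit with the log2 ACT1 ratio of 3' to 5' signal as a covariate and one without 4 arrays that deviated together were added. Relations between the controls and the shared deviation of arrays were tested by exact permutation within groups, two-sided, over 15552 arrangements.

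The procedure was tested on simulated data of 5449 genes and 17 arrays. In the simulated contrast of BM45 at day 5 against day 2 it called 32.8% of genes with a true log2 change of 0.5, 83.6% of those with 1 and 100% of those with 2, and 3 unchanged genes. For the strain difference in the change to day 14 the shares were 19.4%, 76.1% and 98.5%. Camera called the list shifted by -0.5, ergosterol, and 0 of 27 others, which does not vouch for its preset on real data.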

Results

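Gene expression of a pair of commercial Saccharomyces cerevisiae wine yeasts, BM45 and VIN13, was measured by Affymetrix array during fermentation of grape must of the cultivar Colombar with little oxygen. Total RNA came from day 2, in exponential growth, day 5, early in stationary phase, and day 14, late in it. BM45 had 2 arrays at day 2 and 3 each at days 5 and 14, and VIN13 had 3 at each day, 17 in all. Intensities of 5449 genes were compared, and the median gene lay between 866.6 and 1150.4 on the single arrays. The number of arrays per group limits the precision of every value. Nothing in the labels says that the replicates of a group were separate cultures, so the p-values measure only the spread between these samples. Over the 17 arrays the first principal component held 54.9% of the variance and ordered the days, and the second held 17.8% and separated the strains.

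**Figure D1:**
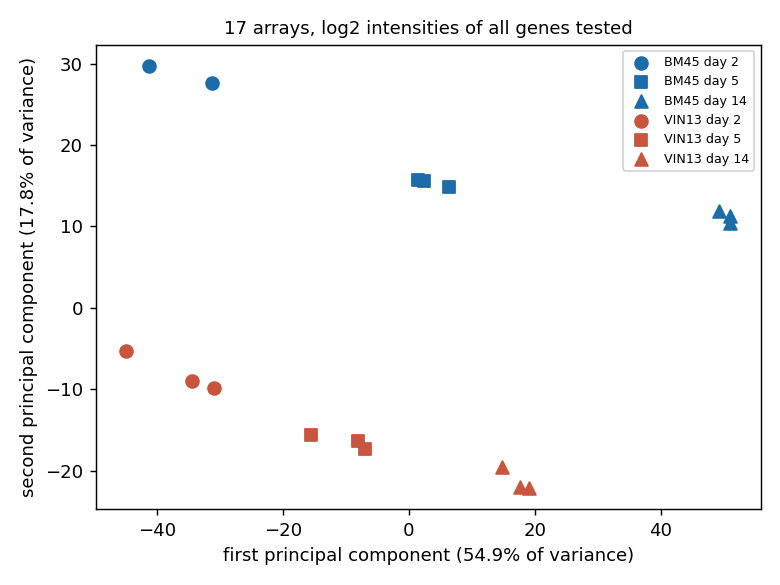
Principal components 1 and 2 of the 17 arrays, from log2 intensities of the tested genes, with the percentage of variance on each axis and 1 point per array (colour for strain, symbol for day). Component 1, with 54.9% of the variance, orders the days, and component 2, with 17.8%, separates BM45 from VIN13.

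Values of genes are differences of group means on the log2 scale ± standard error of the fitted contrast, with adjusted p from limma, and a gene is said to rise, fall or differ only where its adjusted p lay under 0.05. List members not counted in either direction were not called. Counts with limma adjusted over the list alone are in brackets and were the same where none are given. In each comparison of a pair of groups, every array of one group lay above every array of the other for each gene given with a value, which chance gives for 1 gene in 10 with 3 arrays against 3. Seripauperins, hexose transporters, AAD, FLO and THI genes, histones and pairs of ribosomal protein genes are open to cross-hybridisation wherever they are named. Where one group lay below the background bound, a lower bound of the fold as measured is given, that of the bright group's mean against the mean of the dim group with each array set to the higher of its own value and the bound.

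The first time comparison asked how BM45 changed between exponential growth and early stationary phase (n = 2 and 3). Sterol synthesis fell together. 22 of the 23 genes of ergosterol biosynthesis fell. The median was -1.02 (camera adjusted p = 9.02e-11, adjusted p = 0.488 with estimated correlation). Among them HMG1, an HMG-CoA reductase gene, fell by 3.38 ± 0.14 (adjusted p = 1.58e-09), the lanosterol synthase gene ERG7 by 2.84 ± 0.13 and the phosphomevalonate kinase gene ERG8 by 2.68 ± 0.14. Genes of ribosome assembly fell as well, and 59 of the 65 genes of ribosome biogenesis fell (60 fell adjusted over the list alone). The median was -0.92 (camera adjusted p = 8.61e-13, adjusted p = 0.563 with estimated correlation), with UTP13 -2.13 ± 0.26, YTM1 -2.01 ± 0.18 and ERB1 -1.96 ± 0.12. Of the ribosomal proteins themselves, 77 of the 128 genes fell and 2 rose. The median was -0.37 (camera adjusted p = 1.97e-05, adjusted p = 0.595 with estimated correlation), and RPL15B fell by 1.29 ± 0.16.

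In the same interval BM45 raised genes of stress, reserve carbohydrates and respiration. 22 of the 35 genes of the general stress response rose (23 rose adjusted over the list alone). The median was 0.60 (camera adjusted p = 5.99e-08, adjusted p = 0.488 with estimated correlation). HBT1 of this list rose by 4.60 ± 0.31 (adjusted p = 4.99e-08), with RTN2 3.14 ± 0.32 and GRE1 2.97 ± 0.21 beside it, and the Hsp70 gene SSA3 rose by 2.18 ± 0.22. 14 of the 20 genes of trehalose and glycogen metabolism rose. The median was 0.72 (camera adjusted p = 2.20e-05, adjusted p = 0.563 with estimated correlation), with TPS2, of trehalose synthesis, at 1.37 ± 0.19 and GSY2, a glycogen synthase, at 1.34 ± 0.20. 12 of the 16 tricarboxylic acid cycle genes rose. The median was 0.80 (camera adjusted p = 0.000231, adjusted p = 0.563 with estimated correlation), with SDH2 1.78 ± 0.33 and KGD1 1.37 ± 0.18. 16 of the 33 genes of the respiratory chain and ATP synthase rose and 3 fell. The median was 0.27 (camera adjusted p = 0.000231, adjusted p = 0.563 with estimated correlation), although the cytochrome c gene CYC1 fell by 1.53 ± 0.11.

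11 of the 27 heat shock and chaperone genes rose and 4 fell. The median was 0.27 (camera adjusted p = 0.0174, adjusted p = 0.586 with estimated correlation), with HSP78 at 1.07 ± 0.22. 11 of the 20 genes of gluconeogenesis and C2 metabolism rose and 2 fell (12 rose and 2 fell adjusted over the list alone). The median was 0.51 (camera adjusted p = 0.00262, adjusted p = 0.563 with estimated correlation), with the mitochondrial carnitine carrier gene CRC1 at 2.32 ± 0.33. 8 of the 14 genes of peroxisomal beta-oxidation rose and 1 fell. The median was 0.70 (camera adjusted p = 0.00262, adjusted p = 0.563 with estimated correlation), and the catalase gene CTA1 rose by 2.12 ± 0.14. 12 of the 17 genes of vacuolar proteolysis and autophagy rose and 1 fell. The median was 0.51 (camera adjusted p = 0.000515, adjusted p = 0.563 with estimated correlation). 7 of the 17 hexose transporters and sensors rose and 2 fell. The median was 0.29 (camera adjusted p = 0.0171, adjusted p = 0.563 with estimated correlation), and HXT5 rose by 3.56 ± 0.36 and HXT4 by 1.48 ± 0.13. That last call ended without BM45 day 2 replicate 4 (adjusted p = 0.056), and without 4 arrays that deviated together from their group means, BM45 day 2 replicate 4, VIN13 day 2 replicate 1, VIN13 day 5 replicate 3 and VIN13 day 14 replicate 3 (adjusted p = 0.0767). With quantile normalization it ended too (adjusted p = 0.0883), as did that of chaperones (adjusted p = 0.0794).

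Nitrogen genes moved the other way in BM45. 14 of the 22 genes under nitrogen catabolite repression fell and 2 rose. The median was -0.79 (camera adjusted p = 0.00382, adjusted p = 0.563 with estimated correlation). DAL7, of allantoin breakdown, fell by 3.86 ± 0.17 (adjusted p = 1.98e-09), and the allantoinase gene DAL1 and the allantoin permease gene DAL4, below the background bound at day 5, were lower by at least 8.5-fold and at least 3.9-fold. 28 of the 50 genes of amino acid biosynthesis fell and 9 rose (11 rose and 29 fell adjusted over the list alone). The median was -0.42 (camera adjusted p = 0.012, adjusted p = 0.595 with estimated correlation), with ARG3 -2.25 ± 0.21 and LEU9 -1.88 ± 0.15. 12 of the 13 seripauperins fell and 1 rose. The median was -0.91 (camera adjusted p = 0.000952, adjusted p = 0.563 with estimated correlation), with PAU9 -1.18 ± 0.13 and PAU2 -1.13 ± 0.15. Outside these lists' calls, the iron permease gene FTR1 fell by 3.04 ± 0.14, the heme oxygenase gene HMX1 by 2.40 ± 0.18, the agglutinin gene AGA1 by 1.70 ± 0.18, the septin gene SPR28 by 2.35 ± 0.27 and THI13, of thiamine synthesis, by 1.77 ± 0.14, whereas PDC6, a minor pyruvate decarboxylase gene, rose by 1.74 ± 0.37.

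Across the array, 3090 of 5449 genes passed the test, of which 1244 rose and 1846 fell, 889 of them by at least 2-fold. The split was 1751 against 1467 with median centring, 708 against 1719 without BM45 day 2 replicate 4 and 1617 against 1647 without its replicate 2. The signal of the ACT1 control at the 3' end over that at the 5' end, a measure of RNA integrity, was 3.81 ± 2.15 (SD, n = 2) at day 2 and 1.52 ± 0.087 (SD, n = 3) at day 5. Within groups, the median slope per doubling of that ratio was -0.31 for tricarboxylic acid cycle genes, -0.29 for trehalose and glycogen genes, -0.25 for vacuolar genes and 0.16 for ribosome biogenesis, against -0.05 for all genes. Without the 4 arrays the medians were 0.60, 0.53, 0.52 and -1.05 in that order, -1.02 for ergosterol biosynthesis, 0.46 for general stress, 0.29 for gluconeogenesis, 0.08 for chaperones and 0.06 for hexose transporters. With the ACT1 ratio as a covariate the split was 758 against 1697 and the same medians were 0.42, 0.45, 0.33, -0.87, -1.09, 0.38, 0.28, 0.00 and 0.05. The ribosomal protein median relative to all genes was -0.29, -0.12 without the 4 arrays and -0.10 with the covariate.

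**Figure D2:**
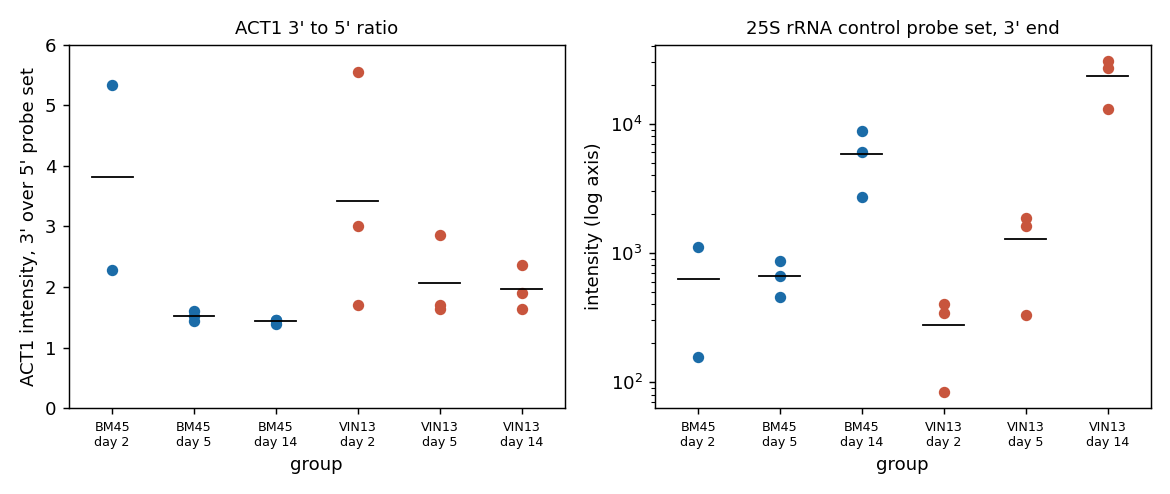
Left, ratio of 3' to 5' intensity of the ACT1 control, and right, intensity of the 25S ribosomal RNA control on a log axis, with 1 point per array in each strain and day and a bar at the group mean. The ACT1 ratio is highest at day 2, with means of 3.81 in BM45 and 3.42 in VIN13, and the ribosomal RNA signal is highest at day 14.

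VIN13 was compared over the same interval, exponential to early stationary phase (n = 3 and 3). Sterol synthesis again fell, and 22 of the 23 ergosterol genes fell. The median was -1.01 (camera adjusted p = 2.57e-15, adjusted p = 0.394 with estimated correlation), with ERG8 -2.32 ± 0.13, ERG6 -2.27 ± 0.14 and ERG7 -2.20 ± 0.12. ARE2, a sterol acyltransferase gene, fell by 3.47 ± 0.11 (adjusted p = 2.98e-11). 41 of the 65 genes of ribosome biogenesis fell (45 fell adjusted over the list alone). The median was -0.51 (camera adjusted p = 1.19e-08, adjusted p = 0.743 with estimated correlation), with RRB1 -1.24 ± 0.13 and UTP13 -1.19 ± 0.23. Among the largest rises were HBT1 3.45 ± 0.28 and GRE1 3.24 ± 0.19, both in the general stress list, OPT2, an oligopeptide transporter gene, at 3.23 ± 0.29, SHH3 at 2.92 ± 0.22 and HXT5 at 2.83 ± 0.32.

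18 of the 35 genes of the general stress response rose (19 rose adjusted over the list alone). The median was 0.33 (camera adjusted p = 3.05e-07, adjusted p = 0.494 with estimated correlation). 4 of the 27 chaperone genes rose. The median was 0.18 (camera adjusted p = 0.00288, adjusted p = 0.743 with estimated correlation), with SSA3 1.86 ± 0.19 and HSP12 1.44 ± 0.11. 11 of the 20 genes of trehalose and glycogen metabolism rose. The median was 0.41 (camera adjusted p = 0.00013, adjusted p = 0.743 with estimated correlation), with TPS2 0.71 ± 0.17 and TPS1 0.68 ± 0.19. 12 of the 16 tricarboxylic acid cycle genes rose (13 rose and 1 fell adjusted over the list alone). The median was 0.58 (camera adjusted p = 0.000188, adjusted p = 0.743 with estimated correlation), and IDH1, of isocitrate dehydrogenase, rose by 1.26 ± 0.20. 14 of the 33 respiratory genes rose and 2 fell. The median was 0.21 (camera adjusted p = 0.00013, adjusted p = 0.494 with estimated correlation), with ATP4 1.18 ± 0.11 and NDE2 1.15 ± 0.15. 9 of the 20 genes of gluconeogenesis and C2 metabolism rose and 1 fell (12 rose and 1 fell adjusted over the list alone). The median was 0.39 (camera adjusted p = 0.000188, adjusted p = 0.73 with estimated correlation), with CRC1 at 1.75 ± 0.29. 11 of the 27 genes of the cell cycle, DNA replication and histones rose and 5 fell (13 rose and 5 fell adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.0168, adjusted p = 0.743 with estimated correlation). CTA1 rose by 1.96 ± 0.13, the aryl alcohol dehydrogenase gene AAD10 by 2.59 ± 0.11 and ZPS1, a gene induced by low zinc, by 2.42 ± 0.30.

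19 of the 128 ribosomal protein genes fell and 1 rose (1 rose and 10 fell adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.00302, adjusted p = 0.854 with estimated correlation), and RPS14B rose by 0.91 ± 0.13. 4 of the 17 genes of vacuolar proteolysis and autophagy rose. The median was 0.27 (camera adjusted p = 0.0168, adjusted p = 0.833 with estimated correlation). Without VIN13 day 2 replicate 1 both of these calls ended (adjusted p = 0.584 and 0.219). Among nitrogen genes DAL4 rose by 1.52 ± 0.23 and DAL1 fell by 1.31 ± 0.24, and the basic amino acid permease gene ALP1 fell by 3.08 ± 0.20. AMF1 fell by 2.85 ± 0.13, PRM7 by 2.73 ± 0.15, AGA1 by 1.61 ± 0.16 and SPR28 by 1.68 ± 0.24. FTR1 fell by 2.22 ± 0.13, the copper transporter gene CCC2 by 1.61 ± 0.11, SAM2, of S-adenosylmethionine synthesis, by 1.28 ± 0.10 and the methionine synthase gene MET6 by 1.09 ± 0.13.

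In VIN13, 2052 of 5449 genes passed the test, of which 842 rose and 1210 fell, 299 of them by at least 2-fold. The split was 1125 against 1033 with median centring and 664 against 782 without VIN13 day 5 replicate 1. The ACT1 ratio was 3.42 ± 1.96 at day 2 and 2.07 ± 0.688 at day 5 (SD, n = 3). Without the 4 arrays the medians were -1.05 for ergosterol biosynthesis, -0.34 for ribosome biogenesis, 0.19 for general stress, 0.24 for trehalose and glycogen, 0.36 for the tricarboxylic acid cycle, 0.15 for chaperones, -0.09 for ribosomal proteins (adjusted p = 0.602) and 0.05 for vacuolar genes (adjusted p = 0.203). With the ACT1 covariate they were -1.06, -0.42, 0.26, 0.28, 0.34, 0.07, -0.11 and 0.11. The cell cycle call ended with dim genes left out (adjusted p = 0.139).

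**Figure D3:**
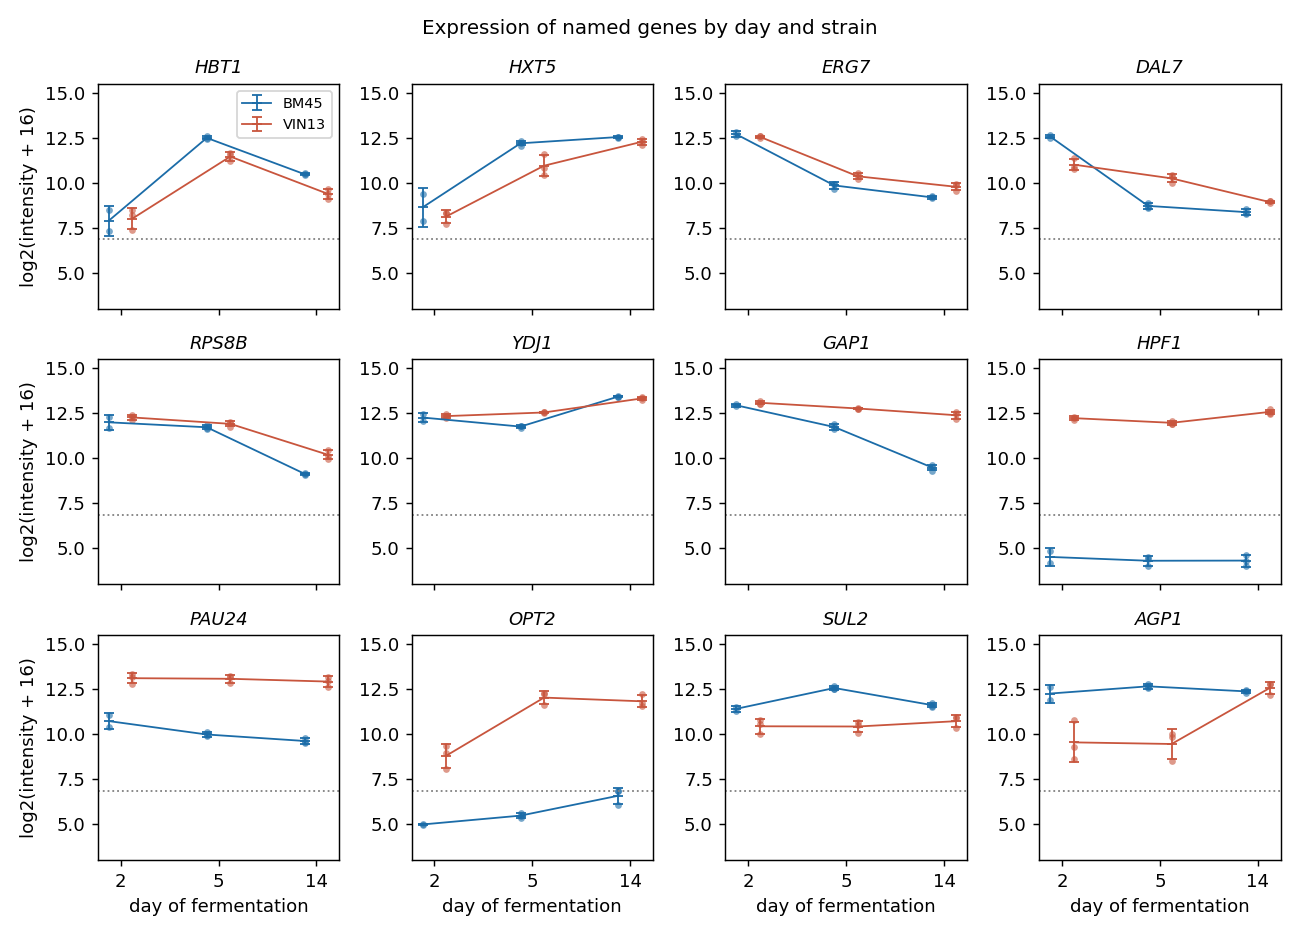
Intensity of 12 named genes as log2(value + 16) at days 2, 5 and 14, equally spaced, with 1 point per array, bars of mean ± SD per strain and day, and a dotted line at the background bound. HPF1 and OPT2 lie below that bound in BM45 at every day and above it in VIN13, whereas ERG7 falls in both strains between days 2 and 5.

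Whether the strains changed differently between days 2 and 5 was tested as the difference of their changes, VIN13 minus BM45, and nitrogen genes differed. 12 of the 22 genes under nitrogen catabolite repression had the higher change in VIN13 and 1 had the lower (13 higher and 1 lower adjusted over the list alone). The median was 0.87 (camera adjusted p = 1.16e-09, adjusted p = 0.541 with estimated correlation), with DAL7 at 3.09 ± 0.23. DAL4 at 4.79 ± 0.34 and DCG1 at 2.93 ± 0.26 lay below the background bound in BM45 at day 5, so these sizes depend on the added constant. The change of seripauperins, which fell in BM45, differed as well, and 8 of the 13 seripauperins differed upward (11 higher adjusted over the list alone). The median was 0.79 (camera adjusted p = 4.85e-07, adjusted p = 0.541 with estimated correlation), with PAU2 1.12 ± 0.21 and PAU9 1.08 ± 0.18. Of the 65 ribosome assembly genes, 13 had the higher change in VIN13 (26 higher adjusted over the list alone). The median was 0.53 (camera adjusted p = 1.16e-09, adjusted p = 0.605 with estimated correlation), with UTP5 1.19 ± 0.22 and ERB1 1.02 ± 0.16. 12 of the 50 genes of amino acid biosynthesis had the higher change in VIN13 and 2 had the lower (19 higher and 2 lower adjusted over the list alone). The median was 0.43 (camera adjusted p = 2.48e-05, adjusted p = 0.605 with estimated correlation), with GDH1 1.80 ± 0.31 and ARG3 1.60 ± 0.28, and SER3 at -1.38 ± 0.14 against the trend.

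By camera, 7 further lists had lower changes in VIN13. 1 of the 14 genes of peroxisomal beta-oxidation had the lower change. The median was -0.41 (camera adjusted p = 0.00266, adjusted p = 0.605 with estimated correlation). 0 of the 17 genes of vacuolar proteolysis and autophagy were called by limma, with 6 at unadjusted p under 0.05. The median was -0.27 (camera adjusted p = 0.00714, adjusted p = 0.605 with estimated correlation). 2 of the 35 genes of the general stress response had the lower change. The median was -0.11 (camera adjusted p = 0.00285, adjusted p = 0.605 with estimated correlation). 1 of the 20 genes of trehalose and glycogen metabolism had the lower change. The median was -0.23 (camera adjusted p = 0.00714, adjusted p = 0.785 with estimated correlation). 3 of the 17 hexose transporters and sensors had the lower change and 1 had the higher change (2 higher and 3 lower adjusted over the list alone). The median was -0.34 (camera adjusted p = 0.0203, adjusted p = 0.605 with estimated correlation). 3 of the 22 genes of sulfate assimilation and methionine had the lower change (1 higher and 4 lower adjusted over the list alone). The median was -0.40 (camera adjusted p = 0.00466, adjusted p = 0.605 with estimated correlation). 0 of the 16 tricarboxylic acid cycle genes were called by limma, with 4 at unadjusted p under 0.05. The median was -0.20 (camera adjusted p = 0.0414, adjusted p = 0.785 with estimated correlation). Changes were higher in VIN13 for a pair of lists. 2 of the 128 ribosomal protein genes had the higher change (0 adjusted over the list alone, with 26 at unadjusted p under 0.05). The median was 0.21 (camera adjusted p = 0.00206, adjusted p = 0.785 with estimated correlation). 4 of the 23 ergosterol genes had the higher change (5 higher adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.0414, adjusted p = 0.785 with estimated correlation). Among single genes HXT4 differed by -1.68 ± 0.17, CYC1 by 1.46 ± 0.15, HMX1 by 1.95 ± 0.24, HMG1 by 1.39 ± 0.19 and RTN2 by -1.87 ± 0.43. RTN2 was not called without BM45 day 2 replicate 4 (adjusted p = 0.0768) or BM45 day 5 replicate 2 (adjusted p = 0.0531).

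List calls that rested on single arrays were those of general stress, not called without BM45 day 2 replicate 2 (adjusted p = 0.185), hexose transporters, without BM45 day 2 replicate 4 (adjusted p = 0.148, median 0.01), ribosomal proteins, without BM45 day 2 replicate 4 (adjusted p = 0.894) or VIN13 day 2 replicate 3 (adjusted p = 0.287), trehalose and glycogen, without BM45 day 2 replicate 4 (adjusted p = 0.0714), and sulfate assimilation, without VIN13 day 2 replicate 1 (adjusted p = 0.116) or VIN13 day 5 replicate 3 (adjusted p = 0.0702). The call of ergosterol biosynthesis ended with any 1 of 8 arrays left out (adjusted p from 0.0515 to 0.139), and that of the tricarboxylic acid cycle with any 1 of 5 arrays left out (adjusted p from 0.0668 to 0.167). Calls of hexose transporters, sulfate assimilation and ergosterol biosynthesis ended without the 4 arrays (adjusted p = 0.133, 0.394 and 0.204), with medians of -0.14, 0.09, opposite in sign, and 0.26, and that of general stress was -0.18. With the ACT1 covariate the medians were -0.04 for general stress, -0.10 for trehalose and glycogen, -0.07 for the tricarboxylic acid cycle and -0.19 for hexose transporters. In all, 472 of 5449 genes passed the test, of which 356 had the higher change in VIN13 and 116 the lower, 126 of them by at least 2-fold. The split was 238 against 224 with median centring.

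With 1 array left out the number of genes called in this difference ranged from 184 without BM45 day 5 replicate 2 to 1348 without BM45 day 2 replicate 2, where the majority turned, with a split of 581 against 767. Without the 4 arrays it was 1494, split 1002 against 492, and with quantile normalization the split was 294 against 278. Of the genes called in either strain over this interval, 616 rose and 1035 fell in both, where independent calls would give 192.2 and 409.9, and 14 were called in opposite directions. The changes correlated across genes with r = 0.799, and genes are not independent replicates. The deviation shared by the arrays, which followed the ACT1 ratio, correlated across genes with the change in BM45 at r = -0.578, with that in VIN13 at -0.433 and with their difference at 0.468.

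From day 5 to day 14 BM45 was compared between early and late stationary phase (n = 3 and 3). The median gene changed by -0.19, so values of genes and lists here are relative to it, and bounds of folds are not. The uncharacterised gene YMR244W rose by 3.99 ± 0.11 (adjusted p = 4.88e-12). AGP2, a plasma membrane permease gene, and LDS1, a spore wall gene, lay below the background bound at day 5 and were higher by at least 8.21-fold and at least 3.12-fold at day 14. PMA2, a proton pump gene, fell by 3.30 ± 0.59, PDC6 by 3.22 ± 0.33, ETR1, of mitochondrial fatty acid synthesis, by 2.60 ± 0.14, and YPT6, of Golgi traffic, by 2.47 ± 0.17.

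Ribosomal protein genes fell in BM45, and 108 of the 128 measured fell and 2 rose (3 rose and 108 fell adjusted over the list alone). The median was -0.56 (camera adjusted p = 6.66e-11, adjusted p = 0.833 with estimated correlation). RPS8B changed by -2.40 ± 0.15, RPS1A by -1.98 ± 0.15 and RPS0B by -1.92 ± 0.23. 42 of the 65 genes of ribosome biogenesis fell and 6 rose. The median was -0.33 (camera adjusted p = 0.025, adjusted p = 0.897 with estimated correlation), and PWP1 and UTP8, below the bound at day 14, were lower by at least 3.07-fold and at least 1.89-fold. 22 of the 23 ergosterol genes fell. The median was -1.16 (camera adjusted p = 1.75e-06, adjusted p = 0.833 with estimated correlation), with ERG20 -2.22 ± 0.16, ERG13 -1.72 ± 0.16 and MVD1 -1.71 ± 0.19. 18 of the 27 chaperone genes rose and 3 fell. The median was 0.69 (camera adjusted p = 9.19e-05, adjusted p = 0.833 with estimated correlation), with the Hsp70 exchange factor gene FES1 at 2.06 ± 0.12, the Hsp40 gene YDJ1 at 1.87 ± 0.10 and the Hsp90 cochaperone gene AHA1 at 1.52 ± 0.12.

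10 of the 20 genes of meiosis and spores rose and 4 fell. The median was 0.66 (camera adjusted p = 0.0137, adjusted p = 0.833 with estimated correlation). SPR28 rose by 2.73 ± 0.24, the meiotic recombinase gene DMC1 by 2.15 ± 0.12 and SPO11, of meiotic double-strand breaks, by 1.95 ± 0.14. 8 of the 17 markers of mating and haploid cells rose and 3 fell. The median was 0.42 (camera adjusted p = 0.025, adjusted p = 0.833 with estimated correlation), with the a-factor gene MFA1 at 2.49 ± 0.21. MFA2, below the bound at day 5, was higher by at least 1.27-fold. 10 of the 20 genes of gluconeogenesis and C2 metabolism rose and 4 fell. The median was 0.64 (camera adjusted p = 0.032, adjusted p = 0.897 with estimated correlation). 9 of the 17 hexose transporters and sensors rose and 2 fell. The median was 0.54 (camera adjusted p = 0.032, adjusted p = 0.833 with estimated correlation), and HXT4 fell by 1.34 ± 0.11. LEU2 changed by -2.26 ± 0.29, ILV5 by -2.10 ± 0.26, BAT1 by -1.94 ± 0.28, the general amino acid permease gene GAP1 by -2.06 ± 0.11 and DAL80, a repressor of nitrogen genes, by -1.21 ± 0.14.

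CIT3, a mitochondrial citrate synthase gene, rose by 2.68 ± 0.11, whereas LSC2, of succinyl-CoA ligase, changed by -1.84 ± 0.13. Falls were also seen for the pyruvate decarboxylase gene PDC5 at -1.31 ± 0.16, the glutamate decarboxylase gene GAD1 at -2.12 ± 0.17, RTN2 at -2.15 ± 0.29, TPS3 at -1.48 ± 0.14, the glycogen phosphorylase gene GPH1 at -1.37 ± 0.15, EEB1, of ethyl ester synthesis, at -1.66 ± 0.09, and the vacuolar peptidase gene APE3 at -1.27 ± 0.12. The G1 cyclin gene CLN1 fell below the bound, by at least 2.7-fold. With dim genes left out the calls of hexose transporters, ribosome biogenesis, gluconeogenesis, mating and meiosis ended (adjusted p = 0.625, 0.0807, 0.161, 0.476 and 0.0999), and the mating median as fitted turned from 0.23 to -0.06. With quantile normalization those of hexose transporters and ribosome biogenesis ended (adjusted p = 0.138 and 0.237), and with median centring that of gluconeogenesis (adjusted p = 0.068). In total 3655 of 5449 genes passed the test, of which 1304 rose and 2351 fell, 1208 of them by at least 2-fold. The split was 1794 against 1890 with median centring. Ratios of 3' to 5' control signal did not move alike, with log2 changes (SE) of -0.09 ± 0.41 for ACT1, 0.00 ± 0.29 for RIP1, -0.46 ± 0.23 for SPT15, 0.07 ± 0.03 for TDH1, 1.07 ± 0.43 for URA3 and 1.12 ± 0.53 for WBP1. Arrays of the days did not overlap for the last 4.

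In VIN13 from day 5 to day 14 (n = 3 and 3), with values as fitted, 105 of the 128 ribosomal protein genes fell (108 fell adjusted over the list alone). The median was -0.62 (camera adjusted p = 1.34e-24, adjusted p = 0.778 with estimated correlation), with RPS0B -1.95 ± 0.23, RPS28B -1.82 ± 0.20 and RPS8B -1.72 ± 0.15. The fitted BM45 median was -0.76. YMR244W rose here too, by 4.29 ± 0.11 (adjusted p = 8.36e-13). Other rises were those of the amino acid permease gene AGP1 at 3.11 ± 0.45, CAT8, a regulator of gluconeogenesis, at 2.42 ± 0.20 and GIT1, of glycerophosphodiester uptake, at 2.25 ± 0.34. 32 of the 65 genes of ribosome biogenesis fell and 3 rose (3 rose and 38 fell adjusted over the list alone). The median was -0.38 (camera adjusted p = 3.18e-05, adjusted p = 0.778 with estimated correlation), with YTM1 at -1.10 ± 0.16.

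16 of the 23 ergosterol genes fell (17 fell adjusted over the list alone). The median was -0.40 (camera adjusted p = 4.97e-05, adjusted p = 0.778 with estimated correlation), with ERG20 -1.42 ± 0.16, MVD1 -1.35 ± 0.19 and ERG13 -1.20 ± 0.16. 32 of the 50 genes of amino acid biosynthesis fell and 2 rose (4 rose and 34 fell adjusted over the list alone). The median was -0.47 (camera adjusted p = 2.87e-06, adjusted p = 0.778 with estimated correlation), with LEU2 -1.83 ± 0.29, ILV5 -1.64 ± 0.26 and ARO4 -1.54 ± 0.21, and the branched-chain aminotransferase gene BAT1 at -1.90 ± 0.28. 14 of the 22 genes under nitrogen catabolite repression fell (1 rose and 14 fell adjusted over the list alone). The median was -0.45 (camera adjusted p = 0.00283, adjusted p = 0.778 with estimated correlation). The allantoin genes DAL4 and DAL1, below the bound at day 14, were lower by at least 3.63-fold and at least 2.69-fold. 11 of the 27 chaperone genes rose and 2 fell. The median was 0.29 (camera adjusted p = 0.0035, adjusted p = 0.778 with estimated correlation), with YDJ1 0.78 ± 0.10, AHA1 0.71 ± 0.12 and FES1 0.67 ± 0.12. 6 of the 20 genes of meiosis and spores rose and 2 fell. The median was 0.30 (camera adjusted p = 0.0407, adjusted p = 0.778 with estimated correlation), with SPR28 1.63 ± 0.24, SPO11 1.01 ± 0.14 and DMC1 0.95 ± 0.12. That call ended without VIN13 day 5 replicate 1 (adjusted p = 0.0979), VIN13 day 5 replicate 2 (adjusted p = 0.0671) or VIN13 day 14 replicate 3 (adjusted p = 0.0976), with quantile normalization (adjusted p = 0.0723) and with dim genes left out (adjusted p = 0.0729). The ergosterol median without the 4 arrays was -0.25.

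Among other VIN13 genes MFA1 rose by 1.44 ± 0.21, ARO10, a decarboxylase gene of higher alcohol formation, by 1.80 ± 0.11, CIT3 by 1.20 ± 0.11 and CTA1 by 1.26 ± 0.13. The glycerol genes GPD1 and GPP2 changed by -1.09 ± 0.21 and -1.01 ± 0.14, LSC2 by -1.69 ± 0.13, PDC6 by -1.90 ± 0.33, PMA2 by -2.93 ± 0.59, HBT1 by -2.08 ± 0.28, SIM1 by -2.34 ± 0.37 and CLN1 by -1.55 ± 0.18, and DSE2, a daughter cell glucanase gene, fell below the bound by at least 5.66-fold. In this comparison 2371 of 5449 genes passed the test, of which 1034 rose and 1337 fell, 288 of them by at least 2-fold. The split was 1518 against 1474 without the 4 arrays. Log2 changes (SE) of the control ratios were -0.04 ± 0.41 for ACT1, -0.24 ± 0.29 for RIP1, -0.23 ± 0.23 for SPT15, 0.03 ± 0.03 for TDH1, 0.84 ± 0.43 for URA3 and 0.25 ± 0.53 for WBP1, without overlap of the days for SPT15 and URA3. Between days 5 and 14, 732 genes rose and 1099 fell in both strains, against 247.4 and 576.9 for independent calls, and 66 were called in opposite directions. The changes of the strains correlated across genes with r = 0.719.

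**Figure D4:**
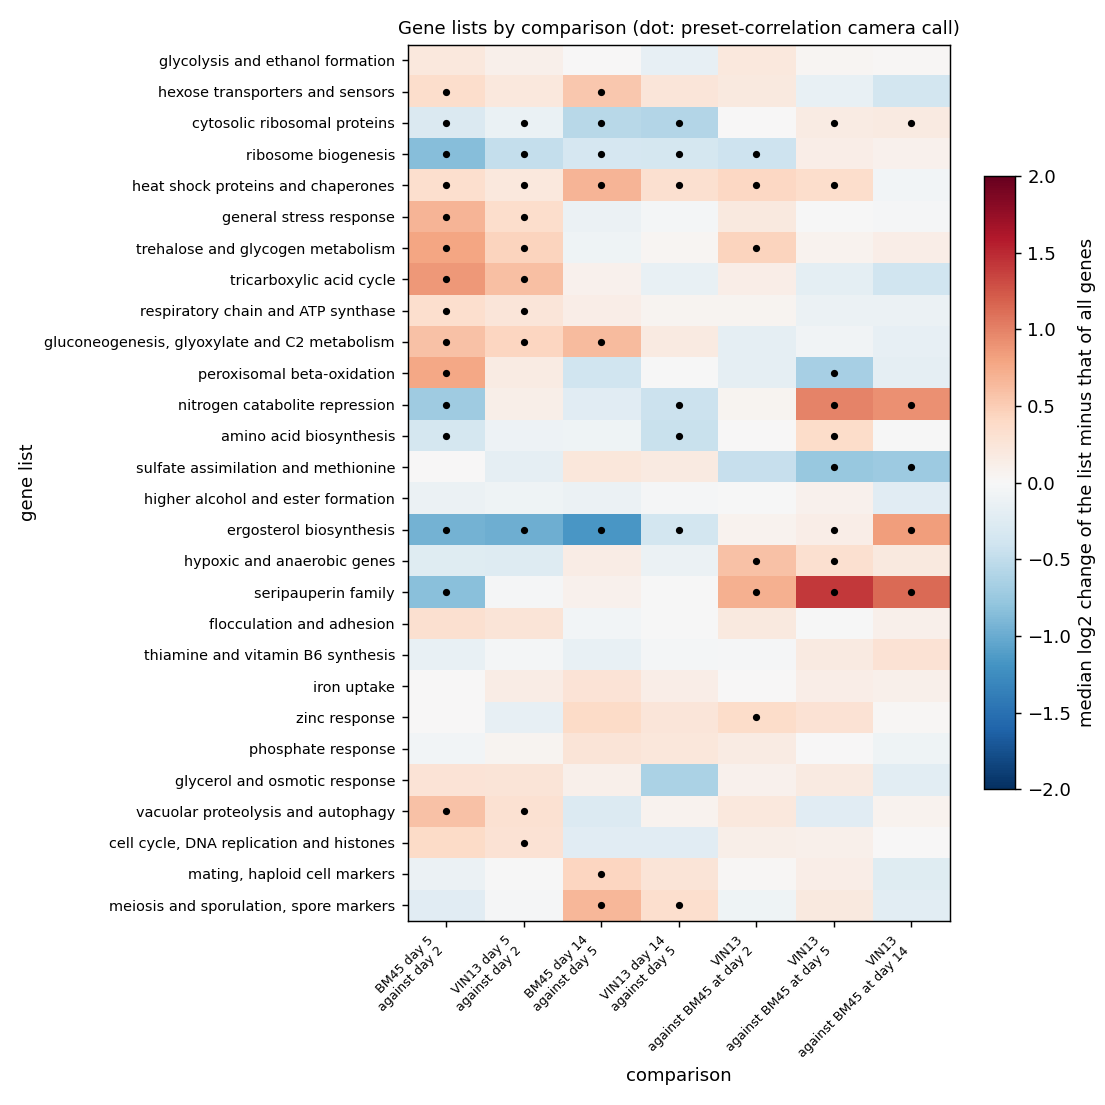
Median log2 difference of each of the 28 gene lists minus the median of all genes, as colour, in 7 comparisons, with a dot where camera with its preset correlation gave an adjusted p under 0.05. Ergosterol biosynthesis is below the other genes in both time comparisons of both strains and above them in VIN13 against BM45 at day 14.

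The difference of the changes from day 5 to day 14, VIN13 minus BM45, had a median of 0.15 over all genes, and values of this comparison are relative to it. Calls and counts of members are those of the values as fitted. Ergosterol genes fell less in VIN13, where 17 of the 23 had the higher change (19 higher adjusted over the list alone). The median was 0.56 (camera adjusted p = 9.23e-05, adjusted p = 0.996 with estimated correlation), with ERG5 1.07 ± 0.14 and ERG2 1.04 ± 0.17. Of 27 chaperone genes, 7 had the lower change and 2 the higher (3 higher and 8 lower adjusted over the list alone). The median was -0.44 (camera adjusted p = 0.00155, adjusted p = 0.996 with estimated correlation), with FES1 -1.34 ± 0.17 and YDJ1 -1.04 ± 0.14. 12 of the 50 genes of amino acid biosynthesis had the lower change and 3 had the higher. The median was -0.41 (camera adjusted p = 0.00105, adjusted p = 0.996 with estimated correlation), with THR1 -1.70 ± 0.30 and LYS9 -1.13 ± 0.18. The amino acid permease genes AGP1 and GAP1 differed by 3.24 ± 0.64 and 1.73 ± 0.16, and the urea permease gene DUR3 by -1.98 ± 0.14.

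EEB1 differed by 1.41 ± 0.13, the peroxisomal fatty acid transporter gene PXA1 by 1.46 ± 0.20, GPH1 by 1.07 ± 0.21, CIT3 by -1.43 ± 0.15 and YHI9 by -2.20 ± 0.19. LDS1 at -3.34 ± 0.28, DAL4 at -2.76 ± 0.32 and the sulfiredoxin gene SRX1 at -2.44 ± 0.41 each lay below the background bound in at least 1 of the 4 groups, so their sizes depend on the added constant. 7 of the 20 genes of meiosis and spores had the lower change in VIN13 and 2 had the higher. The median was -0.33 (camera adjusted p = 0.0474, adjusted p = 0.996 with estimated correlation). 3 of the 11 genes of glycerol and osmotic response had the lower change in VIN13 and 1 had the higher. The median was -0.53 (camera adjusted p = 0.0474, adjusted p = 0.996 with estimated correlation). The glycerol call ended with any 1 of 8 arrays left out (adjusted p from 0.0506 to 0.0919), and that of meiosis with any 1 of 6 arrays left out (adjusted p from 0.0506 to 0.151). With quantile normalization, median centring or dim genes left out both ended (adjusted p = 0.128, 0.152 and 0.0501 for glycerol, 0.0516, 0.154 and 0.235 for meiosis).

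In this difference 1861 of 5449 genes passed the test, 1298 with the higher change in VIN13 and 563 with the lower, and 427 differed by at least 2-fold. The split was 855 against 1018 with median centring. Without the 4 arrays 3178 genes were called. The 25S ribosomal RNA control was 663 ± 205 in BM45 and 1278 ± 831 in VIN13 at day 5, and 5865 ± 3073 and 23439 ± 9153 at day 14 (intensity, SD, n = 3), beside the falls of ribosomal protein and ribosome biogenesis genes in both strains.

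The strains were compared at each day, as VIN13 against BM45, and at day 2 (n = 3 and 2) the median gene differed by -0.13, to which the values of this day are relative, except bounds of folds. The mannoprotein gene HPF1, the Ty element gene YDR316W-B, whose probes match several copies, and YOL159C-A lay below the background bound in BM45 and were higher in VIN13 by at least 41.5-fold, at least 54.4-fold and at least 6.61-fold. OPT2 was higher by at least 3.84-fold and HXT9 by at least 1.32-fold. Below the bound in VIN13 were the permease gene AGP3, lower by at least 2.64-fold, PRY2, of a sterol-binding family, by at least 3.94-fold and the phosphate transporter gene PHO84 by at least 2.57-fold. The formate dehydrogenase gene FDH1 differed by -3.15 ± 0.14 (adjusted p = 1.08e-10) and AGP1 by -2.58 ± 0.50.

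Seripauperins were higher in VIN13 at day 2, and 8 of the 13 measured were higher and 2 lower (9 higher and 2 lower adjusted over the list alone). The median was 0.71 (camera adjusted p = 2.72e-06, adjusted p = 0.677 with estimated correlation), with PAU24 2.52 ± 0.21, PAU3 2.05 ± 0.18 and PAU9 1.72 ± 0.13. 8 of the 19 hypoxic genes were higher and 2 lower. The median was 0.58 (camera adjusted p = 0.000257, adjusted p = 0.688 with estimated correlation). The list shares PAU23 and PAU24 with the seripauperins, and ROX1, a repressor of hypoxic genes, was higher by 1.56 ± 0.26. 13 of the 27 chaperone genes were higher and 1 lower (14 higher and 1 lower adjusted over the list alone). The median was 0.42 (camera adjusted p = 2.72e-06, adjusted p = 0.677 with estimated correlation), with HSP78 1.34 ± 0.22 and FES1 1.04 ± 0.14, but HSP12 at -0.92 ± 0.12. 6 of the 20 genes of trehalose and glycogen were higher and 3 lower (8 higher and 3 lower adjusted over the list alone). The median was 0.44 (camera adjusted p = 0.00516, adjusted p = 0.967 with estimated correlation), with GSY1 1.57 ± 0.17 and GSY2 1.69 ± 0.20. 3 of the 10 genes of the zinc response were higher. The median was 0.37 (camera adjusted p = 0.00914, adjusted p = 0.874 with estimated correlation). 40 of the 65 genes of ribosome biogenesis were lower (44 lower adjusted over the list alone). The median was -0.41 (camera adjusted p = 1.64e-06, adjusted p = 0.967 with estimated correlation), with SSF1 -1.17 ± 0.26, NSR1 -1.02 ± 0.28 and MRD1 -0.85 ± 0.14.

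Single genes higher in VIN13 at day 2 were DAL5 by 1.96 ± 0.20, the serine synthesis gene SER3 by 1.82 ± 0.10 and the vacuolar aminopeptidase gene APE1 by 1.53 ± 0.21. DAL2, the allantoicase gene, differed by -1.61 ± 0.22, GRE1 by -1.61 ± 0.21, the peroxisomal gene SPS19 by -1.08 ± 0.17, MMP1 and MHT1, both of S-methylmethionine use, by -1.08 ± 0.13 and -1.05 ± 0.13, and MET32, a regulator of sulfur genes, by -0.96 ± 0.27. MET32 was not called without BM45 day 2 replicate 4 (adjusted p = 0.0754). At day 2, 1702 of 5449 genes passed the test, of which 433 were higher and 1269 were lower, 252 of them by at least 2-fold. The split was 886 against 647 with median centring, 728 against 838 with quantile normalization, 950 against 1090 without BM45 day 2 replicate 2 and 232 against 1090 without its replicate 4. With only the 5 arrays of this day the test called 108 genes, and camera called 11 lists instead of 6 without VIN13 day 2 replicate 1.

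At day 5 (n = 3 and 3) VIN13 was higher than BM45 for nitrogen genes, seripauperins and amino acid genes, and lower for sulfur genes. 15 of the 22 genes under nitrogen catabolite repression were higher and 3 lower (16 higher and 3 lower adjusted over the list alone). The median was 0.92 (camera adjusted p = 2.03e-10, adjusted p = 0.31 with estimated correlation). DAL5 was higher by 2.68 ± 0.18 and DAL4, below the bound in BM45, by at least 3.63-fold. 11 of the 13 seripauperins were higher and 1 lower (12 higher and 1 lower adjusted over the list alone). The median was 1.34 (camera adjusted p = 6.90e-14, adjusted p = 0.161 with estimated correlation), with PAU24 3.10 ± 0.19, PAU3 2.80 ± 0.16 and PAU9 2.67 ± 0.12. 18 of the 50 genes of amino acid biosynthesis were higher and 3 lower (20 higher and 3 lower adjusted over the list alone). The median was 0.30 (camera adjusted p = 1.72e-07, adjusted p = 0.44 with estimated correlation), with ARG1 0.98 ± 0.11 and LYS4 0.97 ± 0.09. 17 of the 22 genes of sulfate assimilation and methionine were lower (1 higher and 17 lower adjusted over the list alone). The median was -0.83 (camera adjusted p = 1.12e-07, adjusted p = 0.44 with estimated correlation), with the sulfate permease gene SUL2 at -2.14 ± 0.21, MET28 at -1.67 ± 0.27 and MET17 at -1.21 ± 0.14.

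9 of the 14 genes of peroxisomal beta-oxidation were lower and 1 higher. The median was -0.73 (camera adjusted p = 0.000103, adjusted p = 0.498 with estimated correlation), with SPS19 -1.48 ± 0.15, PXA1 -1.13 ± 0.14 and FOX2 -1.06 ± 0.13. 13 of the 27 chaperone genes were higher and 2 lower. The median was 0.27 (camera adjusted p = 0.000100, adjusted p = 0.44 with estimated correlation), with FES1 1.32 ± 0.12, CPR6 1.03 ± 0.10 and BTN2 0.91 ± 0.15. 7 of the 23 ergosterol genes were higher and 1 lower (9 higher and 2 lower adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.00428, adjusted p = 0.804 with estimated correlation), with HMG1 1.30 ± 0.13 and ERG13 0.71 ± 0.16. 6 of the 19 hypoxic genes were higher (7 higher adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.000385, adjusted p = 0.44 with estimated correlation), and AUS1, a sterol importer gene, was higher by 1.58 ± 0.20. 12 of the 128 ribosomal protein genes were higher and 1 lower (4 higher adjusted over the list alone). The median was 0.10 (camera adjusted p = 5.46e-05, adjusted p = 0.878 with estimated correlation). HPF1, YDR316W-B and OPT2 were higher by at least 34.6-fold, at least 33-fold and at least 36.1-fold. AAD6, ZNF1, a regulator of respiratory growth, and AGP3 were lower by at least 2.49-fold, at least 1.58-fold and at least 1.2-fold.

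CYC1 was higher in VIN13 by 1.24 ± 0.10, NDE1, an external NADH dehydrogenase gene, by 1.38 ± 0.18, HMX1 by 1.47 ± 0.16, GSY1 by 1.72 ± 0.15 and ZPS1 by 2.25 ± 0.30, while AGP1 differed by -3.20 ± 0.45, GRE1 by -1.47 ± 0.19 and HXT1 by -1.04 ± 0.14. At day 5, 1373 of 5449 genes passed the test, of which 539 were higher and 834 were lower, 215 of them by at least 2-fold. The split was 802 against 634 with median centring and 448 against 471 without VIN13 day 5 replicate 1. The count was 913 without BM45 day 5 replicate 2. It was 2775 without the 4 arrays, which gave medians of 0.02 for ergosterol and 0.40 for hypoxic genes, and the covariate 0.45 for hypoxic genes. The ACT1 ratio was 1.43 to 1.61 in BM45 and 1.65 to 2.86 in VIN13, without overlap.

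At day 14 (n = 3 and 3) VIN13 had higher sterol gene signals than BM45. 22 of the 23 ergosterol genes were higher. The median was 0.91 (camera adjusted p = 3.55e-08, adjusted p = 0.799 with estimated correlation), with the isopentenyl diphosphate isomerase gene IDI1 at 1.53 ± 0.10 (adjusted p = 1.63e-08), ERG13 at 1.42 ± 0.16 and the squalene epoxidase gene ERG1 at 1.25 ± 0.10. 54 of the 128 ribosomal protein genes were higher and 6 lower (53 higher and 6 lower adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.0132, adjusted p = 0.958 with estimated correlation), with RPS1A 1.11 ± 0.15 and RPS8B 1.06 ± 0.15. That call ended with median centring (adjusted p = 0.0622). 15 of the 22 genes under nitrogen catabolite repression were higher and 3 lower (16 higher and 3 lower adjusted over the list alone). The median was 0.98 (camera adjusted p = 0.00344, adjusted p = 0.958 with estimated correlation), with GAP1 at 2.91 ± 0.11 and the GABA permease gene UGA4 at 2.06 ± 0.23. 11 of the 13 seripauperins were higher. The median was 1.20 (camera adjusted p = 3.72e-06, adjusted p = 0.799 with estimated correlation), with PAU24 3.30 ± 0.19, PAU2 2.63 ± 0.14 and PAU9 2.46 ± 0.12. 15 of the 22 genes of sulfate assimilation and methionine were lower and 1 higher. The median was -0.67 (camera adjusted p = 0.000147, adjusted p = 0.958 with estimated correlation), with MET32 -1.51 ± 0.24, MUP1 -1.45 ± 0.32 and MET28 -1.33 ± 0.27.

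HPF1, SEO1, a putative permease gene, and OPT2 were below the bound in BM45 and higher in VIN13 by at least 52.7-fold, at least 6.11-fold and at least 31.3-fold, and ZNF1, LDS1 and PHO84, below it in VIN13, were lower by at least 3.85-fold, at least 3.12-fold and at least 2.69-fold. Higher in VIN13 were PDC6 by 2.08 ± 0.33, PDC5 by 1.74 ± 0.16, AUS1 by 1.88 ± 0.20, GSY1 by 1.62 ± 0.15, GPH1 by 1.56 ± 0.15, EEB1 by 1.27 ± 0.09 and the disaggregase gene HSP104 by 0.97 ± 0.09. Lower were CIC1 -3.22 ± 0.23, SPS19 -1.99 ± 0.15, GRE1 -1.72 ± 0.19 and CIT3 -1.55 ± 0.11, and SNZ1, of vitamin B6 synthesis, at -1.46 ± 0.12, the alcohol dehydrogenase gene ADH2 at -1.10 ± 0.16 and KGD1 at -0.98 ± 0.16. The spore and meiosis genes SPR28, DMC1 and SPO11 differed by -1.25 ± 0.24, -1.10 ± 0.12 and -1.10 ± 0.14. At day 14, 2915 of 5449 genes passed the test, of which 1767 were higher and 1148 were lower, 553 of them by at least 2-fold. The split was 1491 against 1535 with median centring. The ACT1 ratio was 1.40 to 1.45 in BM45 and 1.63 to 2.37 in VIN13, without overlap. With the covariate the ribosomal protein median relative to all genes was 0.11 instead of 0.19, and the ergosterol median was 0.94.

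Averaged over the days with equal weight, VIN13 differed from BM45 in 2683 of 5449 genes, 1157 higher and 1526 lower, 170 of them by at least 2-fold. The split was 1455 against 1310 with median centring. Sulfur genes were lower, and 19 of the 22 genes of sulfate assimilation and methionine were lower and 1 higher. The median was -0.74 (camera adjusted p = 4.84e-06, adjusted p = 0.701 with estimated correlation), with SUL2 -1.34 ± 0.12 and MET32 -1.19 ± 0.15. 11 of the 13 seripauperins were higher and 1 lower (12 higher and 1 lower adjusted over the list alone). The median was 1.01 (camera adjusted p = 4.12e-09, adjusted p = 0.515 with estimated correlation), with PAU24 2.93 ± 0.11 and PAU9 2.24 ± 0.07. 15 of the 22 genes under nitrogen catabolite repression were higher and 5 lower. The median was 0.51 (camera adjusted p = 0.000172, adjusted p = 0.701 with estimated correlation), with DAL5 at 1.97 ± 0.11 and the proline permease gene PUT4 at 1.67 ± 0.15. 18 of the 23 ergosterol genes were higher and 1 lower (19 higher and 1 lower adjusted over the list alone). The median was 0.32 (camera adjusted p = 8.95e-07, adjusted p = 0.701 with estimated correlation), with ERG13 0.76 ± 0.09 and IDI1 0.76 ± 0.06. 8 of the 19 hypoxic genes were higher and 2 lower. The median was 0.29 (camera adjusted p = 0.00285, adjusted p = 0.701 with estimated correlation). 14 of the 27 chaperone genes were higher and 4 lower. The median was 0.25 (camera adjusted p = 0.00592, adjusted p = 0.838 with estimated correlation), with FES1 0.78 ± 0.07 and CPR6 0.78 ± 0.06.

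10 of the 14 genes of peroxisomal beta-oxidation were lower and 1 higher. The median was -0.42 (camera adjusted p = 0.0179, adjusted p = 0.838 with estimated correlation), with SPS19 at -1.56 ± 0.09. That call ended without BM45 day 2 replicate 2 (adjusted p = 0.0571). 31 of the 128 ribosomal protein genes were higher and 5 lower (25 higher and 4 lower adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.00301, adjusted p = 0.838 with estimated correlation). That call ended without BM45 day 2 replicate 2 (adjusted p = 0.154) or VIN13 day 2 replicate 1 (adjusted p = 0.0621). FDH1 differed on average by -2.78 ± 0.07 (adjusted p = 1.36e-13), GRE1 -1.64 ± 0.11, HXT1 -1.16 ± 0.08, GSY1 1.59 ± 0.09, APE1 1.34 ± 0.11 and the adhesin gene FLO11 0.92 ± 0.14. On all 3 days 159 genes were higher and 204 lower in VIN13 (13.9 and 40.9 for independent calls), as genes diverged from the probes could give.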

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

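The tests of neighbouring genes, of probe sets matching several genes, of the ACT1 ratio and of progress of the fermentations, and the settings with the ACT1 ratio as a covariate and without 4 arrays, were chosen only after the result was seen. Progress was first considered over the whole course, and that test was narrowed to days 5 to 14 after its value was known.

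Results listed here are differences between the strains in a change over time, tested as such, and signal outside the genes compared. Their values are as fitted, so those of the later interval include the median shift of 0.15. Between days 2 and 5 the changes differed for 472 genes. Nitrogen genes with a higher change in VIN13 were DAL4 at 4.79, DAL7 at 3.09 and DCG1 at 2.93, of which DAL4 and DCG1 were below the background bound in BM45 at day 5. Amino acid genes differed by 1.80 for GDH1, 1.60 for ARG3 and -1.38 for SER3. The ribosome assembly genes UTP5 and ERB1 differed by 1.19 and 1.02, and the seripauperins PAU2 and PAU9 by 1.12 and 1.08. Further values were 1.95 for HMX1, 1.46 for CYC1, 1.39 for HMG1, -1.68 for HXT4 and -1.87 for RTN2. RTN2 was not called without BM45 day 2 replicate 4 (limma adjusted p = 0.0768) or BM45 day 5 replicate 2 (0.0531).

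Between days 5 and 14 the changes differed for 1861 genes. Permease genes differed by 3.39 for AGP1, 1.88 for GAP1, -1.83 for DUR3 and -2.61 for DAL4. Values were -3.19 for LDS1, -2.29 for SRX1 and -2.05 for YHI9, and LDS1, DAL4 and SRX1 each had a group below the background bound. The sterol genes ERG5 and ERG2 differed by 1.22 and 1.19, the chaperone genes FES1 and YDJ1 by -1.19 and -0.89, and the amino acid genes THR1 and LYS9 by -1.55 and -0.98. EEB1 differed by 1.56, PXA1 by 1.61, GPH1 by 1.22 and CIT3 by -1.28. Outside the genes compared, the 25S ribosomal RNA control had mean intensities of 5865.1 in BM45 and 23438.9 in VIN13 at day 14, above the background bound of 100.7.

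A total of 12 genes, among them HPF1, OPT2, SEO1 and REE1, lay near background in BM45 on every day and bright in VIN13, and 0 genes showed the reverse by the same bounds. Probe sets matching several genes are 41.7% of them against 2.1% of all tested genes (Fisher's exact p = 2.94e-06). Extra matches cannot lower signal in BM45, and the other 7 genes have none. A gene missing or diverged from the probes in BM45 cannot be told apart from one that is not expressed: 4 of the 12 had another within 2 genes on the chromosome, against a 95th percentile of 2 in matched draws (permutation p = 0.02 over 10000 draws). Counting YAR009C and YAR010C, which belong to 1 mobile element, once leaves 2 of 11 (permutation p = 0.19). Expression differing between the strains stays open as untested.

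Arrays deviated together from their group means, and the first component of these deviations held 52.3% of the variance within groups over 5115 genes. Loss of signal at the 5' end of transcripts is a candidate explanation, since the ACT1 ratio correlated with the component over the 17 arrays at r = 0.947 (rho 0.931, exact permutation p = 0.000129 for each, adjusted p = 0.000903 over 7 relations), and at 0.958 without the 2 farthest arrays. ACT1 was picked after the controls had been viewed, and the ratios of SPT15, URA3, WBP1, RIP1 and TDH1 had r of 0.95, 0.948, 0.922, 0.835 and 0.618 (exact permutation, adjusted p = 0.00495, 0.00225, 0.00495, 0.0185 and 0.0864). Different fermentation progress between days 5 and 14 stays open. Across genes r was -0.1 with the BM45 change of that interval (-0.132 to -0.075 without 1 group), but day 2 arrays deviated most. Progress between days 2 and 5 cannot be told apart from RNA quality, because r was -0.33 with the change from BM45 day 2 replicate 2 and the ACT1 ratio differs between these days, and biological variation among the cultures was not tested.

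The strains' changes from day 5 to day 14 differed for 1861 genes. Array normalization is argued against as the whole cause by 1663 genes called after quantile normalization. Loss of 5' signal cannot be told apart from a difference between the strains: 2472 genes were called with the ACT1 ratio as a covariate, but the strains' changes of that ratio differed by only 0.04 ± 0.58 (log2, SE), so this decides nothing, and those of the WBP1 ratio by -0.87 ± 0.75. Of 100 splits of strain labels within days, 2 gave as many genes, the real one included. They cannot judge chance, as mixed splits put the strain difference into the spread and the other (2789) swaps a whole day. A difference between the strains in late stationary phase stays open as untested, and how far each fermentation had gone was not measured.

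For the strains averaged over the days, 1 of 100 splits, the real one with 2683 genes, gave as many. The highest other, at 1987, swaps a whole day, so chance cannot be judged here either. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. The real splits gave 3655 genes in BM45 from day 5 to 14 (highest other 0), 2052 in VIN13 from day 2 to 5 (35) and 2371 from day 5 to 14 (0), 1373 between the strains at day 5 (0) and 2915 at day 14 (0).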

How the results depend on the processing

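The tests with the ACT1 ratio as a covariate and without the 4 arrays that deviated together were chosen only after the result was seen. No named gene reversed its direction under any alternative run. A called list's median turned in 3 runs, as fitted from 0.23 to -0.062 for mating in BM45 from day 5 to 14 with dim genes left out, and in the difference from day 2 to 5 from -0.34 to 0.014 for hexose transporters without BM45 day 2 replicate 4, against -0.494 without its replicate 2, and from -0.40 to 0.087 for sulfate assimilation without the 4 arrays. None was called where its median turned, and the cause was not tested. All 301 named values stayed called in their direction with pseudocounts of 1 and 64, quantile normalization, median centring, the mean over probe sets, all probe sets in the fit, trend and robust eBayes, the ACT1 covariate and without the 4 arrays. With arrayWeights 2 were no longer called, with only the arrays compared 17 and with 1 array left out 3, and with dim genes left out the 288 still tested stayed called. Counts of genes not given here stayed within 1.5 times the reported ones, with the ACT1 covariate in all 10 comparisons. Lists were tested again only under the settings named for them below, and list counts not given stayed within 1.5 times.

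Stricter bounds call fewer genes by construction. At least 2-fold calls were, for BM45 from day 2 to 5 and 5 to 14, 889 and 1208, for VIN13 299 and 288, for the strains at days 2, 5 and 14 and averaged 252, 215, 553 and 170, and for the differences of the time changes 126 and 427. Among them the majority turned for VIN13 from day 2 to 5, with 153 up and 146 down, and for the strains at days 2 and 5 and averaged, with 133 and 119, 128 and 87, and 102 and 68. An adjusted p under 0.01 left 1225 and 1558 for VIN13 from day 2 to 5 and 5 to 14, 936 and 761 for the strains at days 2 and 5, and 127 and 1031 for the differences. With all probe sets in the fit the difference from day 2 to 5 had 191 genes. With only the arrays compared it had 194, and the strains had 108 at day 2 and 2087 at day 5. arrayWeights, which stopped before convergence, gave 2013 for BM45 from day 2 to 5, 620 and 3356 for the strains at days 2 and 5, and 3498 for the difference from day 5 to 14. Without the 4 arrays, which leaves 1 array of BM45 at day 2, assumed to vary like the other groups, and lowers the spread because they were picked by their deviation, the strains at day 5 had 2775 and the differences 1494 and 3178. Apart from these constructions the cause was not tested.

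Camera with an estimated correlation called 0 lists in each of the 10 comparisons against 87 in all, with 12 at an unadjusted p under 0.05. The strains at day 2 had 6 lists called, but 10 with median centring, 11 with dim genes left out and 10 without the 4 arrays. VIN13 from day 5 to 14 had 7, and 11 without the 4 arrays. BM45 from day 5 to 14 had 8, and 3 with dim genes left out. The averaged strains had 8, and 13 with quantile normalization. The difference from day 5 to 14 had 5, and 3 with quantile normalization, median centring or dim genes left out. The cause of these list changes was not tested.

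Leaving out 1 array gave 2427 to 3264 genes for BM45 from day 2 to 5, 3353 to 3423 from day 5 to 14, 1446 to 2178 and 1895 to 2263 for VIN13, and 1322 to 2040, 913 to 1420, 2464 to 2697 and 2463 to 2913 for the strains at days 2, 5, 14 and averaged. For the differences it gave 184 to 1348 and 1404 to 1989. The 913 came without BM45 day 5 replicate 2. The 1348 came without BM45 day 2 replicate 2 and the 184 without BM45 day 5 replicate 2. Lists called ranged over 14 to 16, 8 to 8, 9 to 13 and 6 to 9 for the time comparisons in that order, 6 to 11, 9 to 9, 5 to 6 and 6 to 9 for the strains, and 9 to 13 and 3 to 5 for the differences. The highest for the strains at day 2, 11, came without VIN13 day 2 replicate 1. The correlation of the strains' changes across genes ranged from 0.709 to 0.818 for days 2 to 5 and from 0.662, without VIN13 day 5 replicate 3, to 0.741 for days 5 to 14. The cause was not tested beyond the smaller number of arrays.

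Replicate numbers were checked for pairing. Arrays of the same number correlated in their deviations from group means at a median r of 0.015 over 31 pairs, from -0.414 to 0.654. That of 89 other pairs was -0.024, and 8 of 17 arrays correlated best with their own number. With strains pooled, pairing stays open. With replicate number as a block within strain the calls were 2025 for BM45 from day 2 to 5 and 52 for the difference from day 2 to 5, and 5 named values were no longer called. The cause was not tested. Signal over background limits the rest: 333 genes had a mean below the background bound, where a fold is at best a bound.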

Other observations

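Only the test without the 4 arrays that deviated together was chosen only after the result was seen.

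Camera called none of the lists given here in the comparisons as reported. Counts adjusted over the list alone are given where they differ. Of glycolysis and ethanol formation, 6 of the 19 genes rose and 1 fell in BM45 from day 2 to 5 (camera adjusted p = 0.0703), and 0 rose and 10 fell from day 5 to 14 (camera adjusted p = 0.342). In VIN13 2 rose and 1 fell (camera adjusted p = 0.194), and 0 rose and 5 fell (camera adjusted p = 0.0991), over the same intervals. In VIN13 from day 5 to 14 the enolase gene ENO2 changed by -0.62 ± 0.16 and TDH3, of glyceraldehyde phosphate dehydrogenase, by -0.47 ± 0.13. ARO8, an aromatic aminotransferase gene, changed by -1.68 ± 0.19 in VIN13 from day 5 to 14.

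Of thiamine and vitamin B6 synthesis, 0 of the 16 genes rose and 8 fell in BM45 from day 2 to 5 (camera adjusted p = 0.183), and 2 rose and 9 fell from day 5 to 14 (camera adjusted p = 0.454). In VIN13 0 rose and 3 fell (camera adjusted p = 0.708), and 0 rose and 2 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.531), over the same intervals. THI22 changed by -1.92 ± 0.13 in BM45 from day 2 to 5, and THI13 differed between the strains by 1.65 ± 0.12 at day 14. Of iron uptake, 2 of the 21 genes rose and 7 fell in BM45 from day 2 to 5 (camera adjusted p = 0.428), and 4 rose and 4 fell from day 5 to 14 (camera adjusted p = 0.38). In VIN13 7 rose and 5 fell (camera adjusted p = 0.844), and 5 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.269), over the same intervals. In VIN13 from day 2 to 5 its median of 0.12 and mean of -0.12 differ in sign, and the reductase gene FRE1 changed by -1.41 ± 0.16. In VIN13 from day 5 to 14 SPL2, of the phosphate response, changed by 0.73 ± 0.13 and the acid phosphatase gene PHO11 by 0.67 ± 0.13. GIT1 rose by 1.97 ± 0.38 in BM45 from day 2 to 5. THI and PHO11 probes are open to cross-hybridisation.

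Under alternative settings camera called glycolysis in VIN13 from day 5 to 14 without the 4 arrays (adjusted p = 0.0299), in BM45 from day 2 to 5 with median centring (adjusted p = 0.016) and for the averaged strains with quantile normalization (adjusted p = 0.0366). Between the strains at day 2 (adjusted p = 0.0544) it was called with quantile normalization, median centring, dim genes left out, without VIN13 day 2 replicate 1 and without the 4 arrays (adjusted p from 0.00598 to 0.04). In the difference from day 2 to 5 thiamine synthesis was called with quantile normalization or dim genes left out (adjusted p = 0.0269 and 0.031), and iron uptake without BM45 day 2 replicate 4 or VIN13 day 2 replicate 3 (adjusted p = 0.0156 and 0.0444).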
